A study of Rattus norvegicus with 12 samples.

How the data were processed

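The series holds 12 libraries of rat uterus, 3 in each of 4 groups, and a table of values per gene for each library. Per the labels' protocols, total RNA was made into polyA-selected TruSeq libraries and sequenced on an Illumina instrument. Strain, treatment, dose, age and time come from the labels. Per the submitters' processing notes, reads were placed on the rat genome build Rnor_5.0, and gene coordinates printed here are those of that build. The aligner, the counting tool and their versions are not given in the sources used here. Of 26312 genes in the deposited tables, 5742 carry an Ensembl identifier as their name and 1113 a numbered locus; a later reference table was used only to match symbols and synonyms. Of the columns, 0 were left unassigned.

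The main unit is the count of total gene reads deposited by the authors, which per the file headers covers exons and introns; unique gene reads, exon reads, exon-exon reads and intron reads are given beside it. RPKM, as deposited and per the file headers, is total exon reads scaled by exon length in kilobases and by total gene reads, and a column named expression value is identical to it. Counts were checked to be whole numbers, and the RPKM was recomputed from the counts. On average 91.9% of gene reads of a library were placed uniquely. The strand used for counting is not stated, so overlapping and antisense genes cannot be separated, and sequence variants between the strains were not analysed here, because no genome sequence was used.

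Counts were tested in R 4.3.3 with edgeR 4.0.16. There filtering by expression at the default settings of filterByExpr kept 15697 genes, which held 99.95% of the reads. Libraries were scaled by TMM factors, and a robust quasi-likelihood model was fitted to the 4 groups with 8 residual degrees of freedom. The common biological coefficient of variation was 0.157. The comparisons were progesterone against oil in HSD, in BN and averaged over strains, BN against HSD under oil and under progesterone, and the strain difference of the progesterone change, which is the BN change minus the HSD change. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes, and called genes are said to have risen or fallen. Per-library levels are in CPM after TMM scaling, and intervals on ratios of low counts and the floor of 3 reads cover counting error only. Log2 changes are printed with an approximate standard error, the absolute change divided by the square root of the quasi-likelihood F statistic. For genes near 0 in a group it is a poor guide to the error of the fold. Group levels are printed as mean ± SD over 3 animals. Libraries labelled as replicates were compared for identity, and a chi-square per degree of freedom between 4.70 and 83.3 separated each pair. No paired design was fitted, because animal numbers and replicate numbers join no libraries across groups. Barcodes do not overlap between any of the 4 groups, and no processing date is given. Strain and a batch that follows strain therefore cannot be told apart, and the same holds for treatment. In 3 of the 4 groups 2 libraries share a barcode, and such a pair cannot have been sequenced in the same pool.

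The following 43 gene lists were fixed before the data were examined: progesterone-responsive uterine genes, estrogen-responsive uterine genes, steroid receptors and cofactors, Hedgehog pathway, glucocorticoid-type response, cell cycle, immediate early genes, circadian clock, vascular growth and tone, extracellular matrix and remodelling, prostaglandin pathway, myometrial contraction-associated genes, decidualization, retinoid metabolism, Wnt pathway, EGF, FGF and IGF ligands and receptors, BMP, TGF-beta and activin pathway, interferon response, cytokines and chemokines, MHC class I and II and antigen presentation, ion and water transport, steroid metabolism, cholesterol and fatty acid synthesis, unfolded protein and heat shock response, and complement. Markers were listed for uterine epithelium, stromal fibroblast, smooth muscle, endothelium, macrophage and dendritic cell, T and NK cell, B and plasma cell, eosinophil, neutrophil and mast cell, red blood cell, adipocyte, mesothelium, squamous cervix or vagina, oviduct and ciliated cell, ovary, skeletal muscle, and nerve and Schwann cell, and as signs of RNA quality mitochondrial oxidative phosphorylation subunits and ribosomal proteins. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the data, and with the rotation test fry, each adjusted over the lists. The fry test asks whether a list moves on balance in a direction, camera whether it moves more than other genes. Calls within a list are counted over all genes and again with adjustment over the list alone. Of all tested genes 39.1% were called in HSD, 25.8% in BN and 48.4% averaged over strains. Between the strains 5.69% were called under oil and 5.73% under progesterone. The counts within lists are to be read against these shares. Among lists called by camera the median, the mean and the direction of the test had the same sign.

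Genes were named by a rule. For the largest changes they needed a symbol, a mean of at least 5 CPM in the higher group and a call: the 10 largest in each direction over both strains whose libraries do not overlap in either strain, the 6 largest in each direction in each strain, the 5 smallest p in each direction of the strain difference, and the 8 largest in each direction between strains called under both treatments. In addition all measured progesterone-responsive genes and the receptors Pgr, Esr1, Esr2 and Nr3c1 are given; Esr2 had too few reads to be tested, and a result withheld for evaluation is left out. Of each other list 2 to 4 of the members with the smallest p are named, together with the genes behind any count of 5 or fewer. Comparisons, tests, lists and alternatives were chosen before the data were examined, with exceptions. Exon reads, scaling by library size alone and removal of a trend on gene length were added after the data were seen. Gene length here means the exon length of a gene throughout. The tests of flagged results and of other observations that are marked so below were also chosen after the result was seen.

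Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter (20683 genes), a filter of 1 CPM in 3 libraries, only the 2 groups compared, limma voom with quality weights, 1 surrogate variable from sva 3.50.0, unique reads, limma on log2(RPKM + 0.5) with 14220 genes, and each library left out in turn. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Each fit that leaves out a library repeats the filter and the spread estimate over all groups. A call lost there need not come from the values of that library alone. Exact tests on 3 against 3 animals cannot go below p = 0.1, and 3 against 3 libraries allow 10 splits.

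The fits were tested on simulated data with 200 planted genes per comparison, 50 at each of the folds 1.5, 2, 3 and 4, among 15697 genes. The share recovered at these folds was 34, 82, 94 and 94% in HSD with 14 false calls, 24, 72, 84 and 98% in BN with 3, and 58, 86, 100 and 100% averaged over strains with 8. For the strain difference it was 6, 42, 80 and 92% with 5 false calls, for the strains under oil 32, 72, 92 and 98% with 8, and under progesterone 36, 70, 98 and 100% with 8. With 44 simulated lists, camera and fry both called the planted list and 0 of the unchanged lists. Genes were drawn independently there, so this cannot show how often lists of correlated genes are called falsely. In a simulation of the size of the response, the median BN to HSD ratio came out at 0.985 for equal responses and at 0.753 for a planted ratio of 0.75. Both strains had the same spread in all of these simulations, whereas the measured spread was larger in HSD. They therefore cannot show whether unequal spread shifts the ratio. Nor can they show how the recovered shares and false calls differ between the strains. The size of the response was also tested by a permutation of strain within treatment, added after the data were seen, over 200 distinct labellings of the libraries and the 7595 genes called across strains. Strain differences shared by both treatments enter the other labellings, so its p is not exact for a difference in response.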

Results

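Gene expression was measured by RNA sequencing in the uterus of ovariectomised rats that had rested for 2 weeks and were 10 weeks old. Animals of 2 strains received progesterone under the skin at 40 µg per g of body weight or sesame oil. The uterus was taken 9 h later. Holtzman Sprague Dawley (HSD) is an outbred stock, and Brown Norway (BN) is an inbred strain, the strain from which the rat reference genome was made. The 4 groups, HSD with oil, HSD with progesterone, BN with oil and BN with progesterone, held 3 animals each, with 1 library per animal. Total gene reads per library ranged from 17435481 to 18880375 in HSD with oil and from 12224142 to 18859636 in HSD with progesterone. They ranged from 11763894 to 15535279 in BN with oil and from 15241366 to 19033254 in BN with progesterone. At these depths 3 reads, the floor used here for detection, correspond to 0.155 to 0.261 CPM, the gene reads of a library scaled to a common depth. Of 26312 genes in the tables, 15697 had enough reads to be tested. Between 19.96 and 25.68% of the gene reads of a library lay in introns. Mitochondrial genes held 5.39 ± 0.392% of reads in HSD with oil, 6.49 ± 1.40% in HSD with progesterone, 4.72 ± 0.389% in BN with oil and 4.76 ± 0.475% in BN with progesterone (mean ± SD, n = 3).

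Treatment and strain separated the 12 libraries on the leading principal components. Component 1 held 45.4% of the variance and placed the 6 progesterone libraries between 28.6 and 56.5 and the 6 oil libraries between -46.1 and -35.0. Component 2 held 22.8% and placed HSD libraries between 21.6 and 33.3 and BN libraries between -36.4 and -24.2. Component 3 held 8.67% and ran within groups, from HSD progesterone replicate 3 at -39.8 to HSD progesterone replicate 2 at 31.2. In replicate 3 the smooth muscle markers lay below the other libraries of its group, with a median log2 deviation of -0.93, and the subunits of mitochondrial oxidative phosphorylation lay above them, with a median of 0.585. The same medians were 0.79 and -0.37 in replicate 2.

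**Figure D1:**
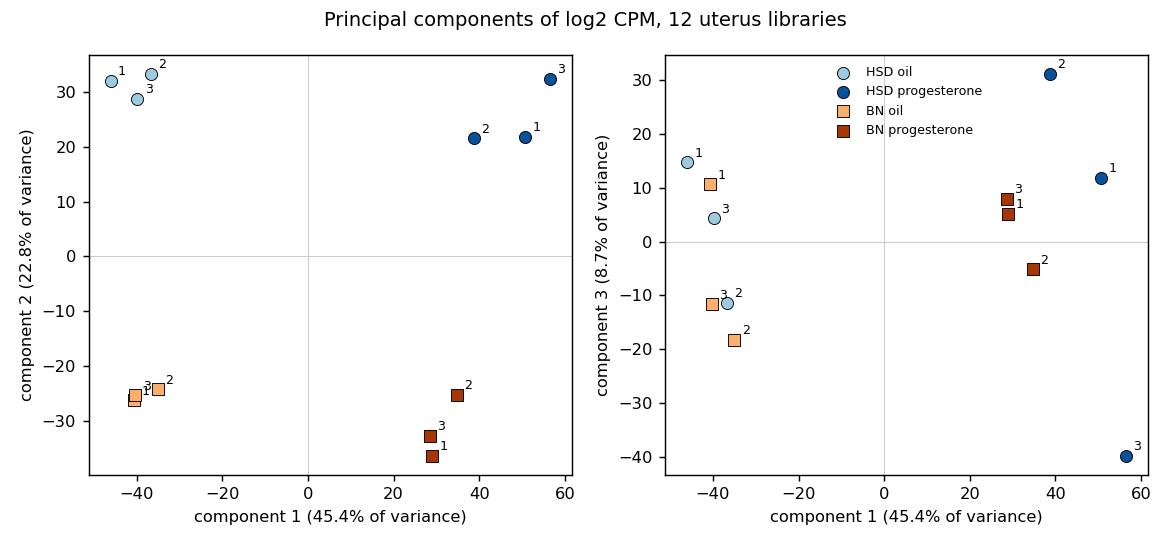
Principal components of the 12 libraries, computed on log2 CPM, with the share of variance on each axis; each point is a library and each colour a group. Component 1 (45.4%) separates progesterone from oil, component 2 (22.8%) separates HSD from BN, and component 3 (8.67%) spreads the HSD progesterone libraries from -39.8 to 31.2.

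Progesterone against oil within HSD asks which uterine genes respond to the hormone within hours. Orm1, an acute-phase plasma glycoprotein (chromosome 5, 83293896 to 83297056), rose from 0.677 ± 0.129 to 1299.9 ± 146 CPM (mean ± SD, n = 3). Calca, which encodes calcitonin and the calcitonin gene-related peptide (chromosome 1, 191158063 to 191162954), rose from 6.52 ± 5.08 to 3950.4 ± 1549 CPM, a fitted fold change of 607. Of its reads 71.8% lay in introns. The largest decrease was in WIF1, a secreted Wnt inhibitor (chromosome 7, 63077688 to 63147645), from 134 ± 78.4 to 3.31 ± 0.704 CPM. Slc26a4, the anion exchanger pendrin (chromosome 6, 59479855 to 59518321), fell from 287 ± 46.6 to 14.9 ± 1.82 CPM. Other large increases, given as log2 fold change ± SE, were in Slc5a5, the sodium/iodide symporter (9.97 ± 0.28), and Pla2g3, a secreted phospholipase A2 (8.24 ± 0.58). They also included Spns3 (8.13 ± 0.31, with 90.2% of reads in introns) and Gal, the neuropeptide galanin (7.86 ± 0.46). Other large decreases were in Mab21l3 (-4.94 ± 0.46), Klhl14 (-4.62 ± 0.40, with 51.3% of reads placed uniquely and so an uncertain level), Hephl1 (-4.51 ± 0.30) and Tmem72 (-4.34 ± 0.38). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 6133 genes, 3193 higher and 2940 lower. Of them 1685 changed at least 2-fold. Scaling by library size alone gave 2355 higher and 4034 lower, and moved the median log2 change of all tested genes from -0.02 to -0.14. That split is relative to this shift. Leaving out any 1 library left between 4774 and 6583 calls, and 5664 without HSD progesterone replicate 3.

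Camera called lists of protein folding, sterol synthesis and mitochondrial respiration genes in HSD. In the list of unfolded protein and heat shock response genes, 18 of 24 measured rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 9.31e-21, and adjusted p = 0.0449 with an estimated correlation). Examples are the endoplasmic reticulum chaperones Hspa5 (2.39 ± 0.15) and Hsp90b1 (2.03 ± 0.14), and Creld2 (2.37 ± 0.14). Of the cholesterol and fatty acid synthesis genes, 20 of 26 measured rose and 0 fell (23 and 0 adjusted over the list alone). Among them were Fdps, farnesyl diphosphate synthase (1.51 ± 0.10), the desaturase Scd (1.64 ± 0.12) and Idi1 (3.71 ± 0.31; camera adjusted p = 3.87e-11, and adjusted p = 0.491 with an estimated correlation). Among nuclear-encoded subunits of mitochondrial oxidative phosphorylation, listed beforehand as a sign of RNA quality, 20 of 23 measured rose and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 2.86e-07, and adjusted p = 0.878 with an estimated correlation). The median level of these subunits, on the log2 scale against the mean of all libraries, was 0.93 in HSD progesterone replicate 3. It was 0.39 and 0.31 in replicates 1 and 2. For progesterone-responsive uterine genes, 14 of 27 measured rose and 3 fell (16 and 3 adjusted over the list alone; camera adjusted p = 1.21e-05, and adjusted p = 0.106 with an estimated correlation). Among genes of a glucocorticoid-type response 8 of 20 measured rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00203, and adjusted p = 0.491 with an estimated correlation). The member that fell was Pdk4, pyruvate dehydrogenase kinase (-1.68 ± 0.26). Fkbp5, Sgk1, Zbtb16 and Tsc22d3, which rose in HSD, belong to the progesterone-responsive list too. So do ERRFI1, Klf9, Klf15 and Per1, and the calls of these lists are therefore not separate. In the Wnt pathway list 3 of 32 measured rose and 13 fell (4 and 14 adjusted over the list alone; camera adjusted p = 0.00318, and adjusted p = 0.507 with an estimated correlation). Its falling members included the ligand Wnt7a (-2.44 ± 0.19), the pathway target Axin2 (-1.13 ± 0.13) and the receptor Lgr5 (-1.0 ± 0.10), together with the secreted inhibitors WIF1 (-5.33 ± 0.46) and Sfrp5 (-2.17 ± 0.31).

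Progesterone against oil within BN asks the same question in the inbred strain. Orm1 rose from 0.898 ± 0.542 to 479 ± 54.9 CPM (n = 3) and Calca from 10.6 ± 3.85 to 2558 ± 194 CPM, a fitted fold change of 243. Lefty1, a secreted antagonist of Nodal signalling (chromosome 13, 104212318 to 104215251), rose from 0.280 ± 0.0913 to 70.7 ± 38.2 CPM. Slc26a4 fell from 169 ± 28.3 to 16.7 ± 1.21 CPM. Gad1, glutamate decarboxylase (chromosome 3, 63479963 to 63519877), fell from 18.6 ± 3.50 to 1.73 ± 0.466 CPM. Further large increases were in Slc5a5 (9.29 ± 0.28), Spns3 (7.56 ± 0.31) and Gal (6.59 ± 0.47). Further large decreases were in WIF1 (-4.54 ± 0.45) and the hemidesmosome collagen Col17a1 (-3.18 ± 0.48), and Bcas1 was among the 6 largest too. Tmem72 (-3.62 ± 0.49) also fell, at a mean under 5 CPM in both BN groups. Cxcl10, an interferon-induced chemokine (chromosome 14, 17126851 to 17129068), fell by 3.54 on the log2 scale in BN (edgeR adjusted p = 0.00170). There the 3 oil libraries held 3.77, 38.7 and 23.7 CPM. In HSD its log2 change was -0.54 ± 0.67, and the strain difference of -3.0 ± 0.93 did not pass the test (edgeR adjusted p = 0.412). The edgeR test called 4045 genes, 2196 higher and 1849 lower, 976 of them changed at least 2-fold. Upper-quartile scaling gave 1759 higher and 2251 lower. The count was 2606 without BN oil replicate 3, 6739 with limma voom and quality weights, and 6186 with 1 surrogate variable.

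Camera called the protein folding and sterol lists above 0 in BN as well, and the interferon and antigen presentation lists below 0. In the unfolded protein and heat shock list 18 of 24 measured rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 2.69e-17, and adjusted p = 0.0727 with an estimated correlation), with Hspa5 at 1.72 ± 0.15 and Creld2 at 1.68 ± 0.14. Among cholesterol and fatty acid synthesis genes 18 of 26 measured rose and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 1.69e-14, and adjusted p = 0.322 with an estimated correlation), with Fdps at 1.23 ± 0.10 and Scd at 1.02 ± 0.12. Of the progesterone-responsive genes 13 of 27 measured rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 3.25e-06, and adjusted p = 0.0854 with an estimated correlation). For oxidative phosphorylation subunits 7 of 23 measured rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.00234, and adjusted p = 0.990 with an estimated correlation). Among glucocorticoid-type genes 7 of 20 measured rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0149, and adjusted p = 0.579 with an estimated correlation). That call ended without BN oil replicate 3, at a camera adjusted p = 0.0519. Fkbp5, Sgk1, ERRFI1 and Klf9, which rose in BN, are in the progesterone-responsive list too. In the Wnt list 2 of 32 measured rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.0384, and adjusted p = 0.636 with an estimated correlation). The camera adjusted p was 0.0571 without HSD progesterone replicate 2, 0.0519 without BN oil replicate 3 and 0.0651 without BN progesterone replicate 1. Among interferon response genes 1 of 23 measured rose and 16 fell (1 and 18 adjusted over the list alone; camera adjusted p = 9.42e-09, and adjusted p = 0.579 with an estimated correlation). Examples are Mx2 (-1.70 ± 0.19), Usp18 (-1.80 ± 0.24) and Oas1a (-0.83 ± 0.13). The member that rose was Rsad2 (0.64 ± 0.22). The list's median level was 0.87 in BN oil replicate 2, against 0.34 and 0.10 in replicates 3 and 1. It was -0.44, -0.43 and -0.44 in the BN progesterone libraries. In HSD 0 of 23 measured rose and 5 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.597). The strain difference is given with the other interactions. Among MHC class I and II and antigen presentation genes 0 of 22 measured rose and 8 fell (0 and 8 adjusted over the list alone; camera adjusted p = 0.000929, and adjusted p = 0.636 with an estimated correlation). Among them were RT1-CE1 (-0.53 ± 0.10), RT1-S3 (-1.18 ± 0.21) and the peptide transporter subunit Tap1 (-1.21 ± 0.26). The list's median level was 0.41 in BN oil replicate 2, against -0.21 and -0.04 in replicates 1 and 3, and that of T and NK cell markers was 0.29 against -0.39 and -0.04.

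Changes in the strains went largely the same way. In both strains 1946 genes rose, where independent lists would share 446.7, and 1528 fell, where independent lists would share 346.3. The strain comparisons share no libraries. Called in opposite directions were 5 genes, Il17re, Myo19, Sftpd, Slc28a3 and RT1-A2. Each of them lost its call in at least 1 strain under some alternative. In HSD the call of Il17re was lost in 7 settings, that of Myo19 in 8, Sftpd in 8 and Slc28a3 in 7. In BN the call of Myo19 was lost in 13 settings, that of Sftpd in 5, and those of Slc28a3 and RT1-A2 in 3 each. Across the 15697 tested genes the log2 changes in HSD and BN correlated with Pearson's r = 0.814 and Spearman's rho = 0.791, and 82.2% had the same sign. Pearson's r was 0.413 with no filter on low counts and between 0.741 and 0.787 with 1 library left out. Those last fits repeat the filter with a smaller group, so more genes with low counts can enter. Genes are not independent replicates, so this is a description. Averaged over the strains, 7595 genes were called by edgeR, 3868 higher and 3727 lower. Scaling by library size alone gave 3129 higher and 4637 lower, with a median change of all genes of -0.10. The largest averaged increases with libraries that do not overlap in either strain also included Scgb1c1 (6.34 ± 0.37), Mmp20, the matrix protease enamelysin (6.08 ± 0.37), and Npy, neuropeptide Y (5.87 ± 0.27, with 23.6% of reads placed uniquely and so an uncertain level). Pla2g3 (7.4 ± 0.41) and Lefty1 (6.96 ± 0.36) were among them too. The largest averaged decreases were in WIF1 (-4.93 ± 0.32), Tmem72 (-3.98 ± 0.30), Slc26a4 (-3.80 ± 0.12), Klhl14 (-3.64 ± 0.26) and Hephl1 (-3.58 ± 0.20). They were followed by Col17a1 (-3.58 ± 0.33), Mab21l3 (-3.56 ± 0.30), Gad1 (-3.44 ± 0.20), Bcas1 (-3.44 ± 0.34) and Pigr, the epithelial receptor that carries polymeric immunoglobulins (-3.12 ± 0.20). With Orm1, Slc5a5, Calca, Spns3 and Gal these are the 10 largest averaged changes in each direction.

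**Figure D2:**
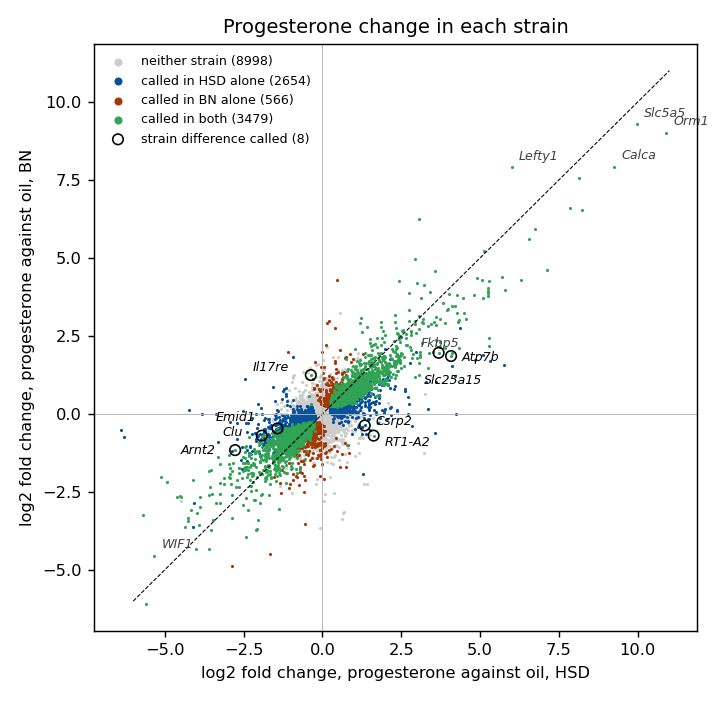
Log2 fold change under progesterone in BN (vertical axis) against that in HSD (horizontal axis) for the 15697 tested genes, with named genes labelled and the genes whose change differed between the strains marked. Most points lie along the diagonal, with Pearson's r = 0.814 across genes, and 0.413 with no filter on low counts.

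**Figure D3:**
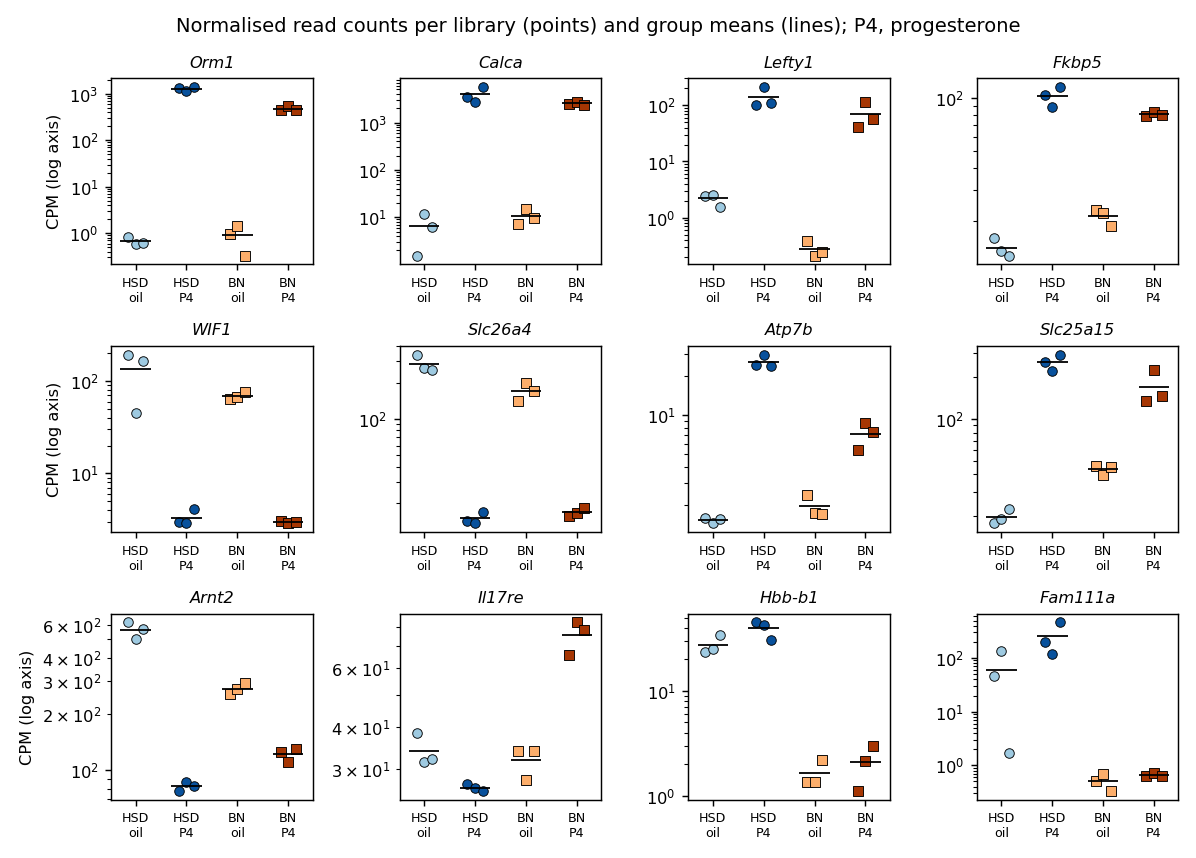
CPM on a log axis in each of the 12 libraries for 12 named genes, with a line at each group's mean (n = 3). Orm1, Calca and Lefty1 rise with progesterone in both strains, Slc26a4 and WIF1 fall, Il17re rises from 31.8 to 75.4 CPM in BN alone, and Hbb-b1 and Fam111a are lower in BN.

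Some known progesterone targets rose in both strains. Fkbp5, a co-chaperone of steroid receptors (chromosome 20, 10177067 to 10219361), rose from 14.1 ± 1.75 to 103 ± 13.3 CPM in HSD and from 21.3 ± 2.33 to 80.9 ± 2.03 CPM in BN (n = 3). Hsd11b2, which inactivates glucocorticoids (chromosome 19, 48341841 to 48347084), rose from 24.1 ± 2.21 to 151 ± 14.5 and from 22.8 ± 2.60 to 104 ± 20.2 CPM. The kinase Sgk1 rose by 1.94 in HSD and 0.99 in BN on the log2 scale, and the activin antagonist Fst by 1.68 and 1.32. In the same order of strains the interleukin 13 decoy receptor Il13ra2 rose by 1.61 and 1.54 and the retinoic acid hydroxylase Cyp26a1 by 3.09 and 1.90. Smaller rises in both strains were in Sox17 (0.50 and 0.44) and the prolactin receptor Prlr (0.70 and 0.68, with 95.6% of reads in introns). Cdkn1c fell by 0.64 and 0.45. Zbtb16 passed the test in HSD (2.63 ± 0.31) and not in BN (0.79 ± 0.28), with a strain difference of -1.84 that did not pass (edgeR adjusted p = 0.193). In HSD Areg (1.82), Lrp2 (0.93), Tsc22d3 (0.55) and Hoxa11_1 (0.97, with no reads placed uniquely) rose, and Ptch1 (-0.41) and Lifr (-0.48) fell. In BN their log2 changes were -0.13, 0.75, 0.16, 0.45, -0.14 and 0.26 and did not pass. Ihh (1.33), the ligand Indian hedgehog, Gata2 (0.29), ERRFI1 (0.41) and Klf9 (0.39) rose in BN. In HSD they changed by 0.49, 0.19, 0.22 and 0.15 and did not pass. None of the strain differences of these 11 genes passed, with edgeR adjusted p values from 0.193 for Zbtb16 to 0.960 for Lrp2. In neither strain did Hand2 (0.16 and 0.16), Nr2f2 (-0.16 and -0.14), Hdc (-0.98 and -0.86), Klf15 (0.32 and 0.13), Per1 (-0.06 and -0.07) or Bmp2 (-0.40 and -0.22) pass. In HSD the calls of Areg, Lrp2, Tsc22d3, Hoxa11_1 and Lifr, and in BN those of Cyp26a1, Il13ra2, Cdkn1c, Sox17, Prlr, Gata2, ERRFI1 and Klf9, were lost under at least 1 alternative setting or left-out library.

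Steroid receptors fell or did not pass. Esr1, the estrogen receptor alpha (chromosome 1, 42667185 to 42931332), fell from 129.7 ± 5.58 to 82.1 ± 4.57 CPM in HSD and from 126 ± 6.39 to 96.9 ± 11.82 CPM in BN (n = 3). The call in BN was lost with exon reads, on log2 RPKM and without BN oil replicate 3 or BN progesterone replicate 3. Pgr, the progesterone receptor (chromosome 8, 7113895 to 7172761), fell from 374 ± 17.3 to 251 ± 19.3 CPM in HSD. In BN its log2 change was -0.16 ± 0.10 (edgeR adjusted p = 0.25). The strain difference of 0.42 did not pass (edgeR adjusted p = 0.493). The glucocorticoid receptor Nr3c1 fell by 0.28 in HSD, and in BN its log2 change was -0.22 ± 0.08. Its call in HSD was lost with only the 2 groups compared, with the gene length trend removed, and without HSD oil replicate 2, HSD oil replicate 3 or HSD progesterone replicate 1. Averaged over the strains, 6 of 21 measured rose and 9 fell (6 and 10 adjusted over the list alone) in the list of steroid receptors and cofactors. The receptor-associated chaperones Ptges3 (1.05 ± 0.09), Fkbp4 (0.99 ± 0.09) and Hsp90aa1 (1.26 ± 0.12) rose. Of the estrogen-responsive uterine genes, 7 of 18 measured rose and 6 fell (7 and 6 adjusted over the list alone). Igf1, a growth factor, stood at 2.66 ± 0.16, the water channel Aqp5 at 1.20 ± 0.10, the mucin Muc1 at -2.66 ± 0.23 and clusterin, Clu, at -1.31 ± 0.09. Neither list was called by camera, with adjusted p of 0.812 and 0.924.

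Camera called none of the signalling, growth and tissue lists named here in the average over strains. In that average 3868 of all 15697 tested genes rose and 3727 fell. Among EGF, FGF and IGF ligands and receptors 7 of 33 measured rose and 12 fell (7 and 12 adjusted over the list alone), with Hbegf at 1.17 ± 0.18 and Spry1 at -0.98 ± 0.13. For the BMP, TGF-beta and activin pathway 7 of 26 measured rose and 8 fell (7 and 9 adjusted over the list alone), with Lefty1 and Fst among the former and Inhbb (-1.51 ± 0.17) and Tgfbi (-0.88 ± 0.10) among the latter. In the Hedgehog pathway 3 of 14 measured rose and 4 fell (3 and 4 adjusted over the list alone), with Ihh at 0.91 ± 0.14, Gli1 at 0.51 ± 0.09 and Gli2 at -0.63 ± 0.12. In the cell cycle list 3 of 32 measured rose and 10 fell (2 and 7 adjusted over the list alone). Mcm7 (-0.60 ± 0.07) and Mcm3 (-0.80 ± 0.14), parts of the replicative helicase, fell. Of the immediate early genes 4 of 21 measured rose and 2 fell (3 and 2 adjusted over the list alone), among them Myc (0.77 ± 0.16) and Fos (1.40 ± 0.34). For vascular growth and tone 4 of 26 measured rose and 7 fell (4 and 7 adjusted over the list alone). The peptides Apln (2.22 ± 0.23) and Adm (-0.96 ± 0.09) moved in opposite directions. In the decidualization list 6 of 23 measured rose and 3 fell (6 and 2 adjusted over the list alone), with Igfbp1 (-2.88 ± 0.58) falling. In BN with progesterone it had 2 reads in all. Of the myometrial contraction genes 2 of 19 measured rose and 3 fell (2 and 3 adjusted over the list alone), with Ptger3, a prostaglandin E receptor, at 0.79 ± 0.12. Among ion and water transport genes 8 of 20 measured rose and 7 fell (8 and 7 adjusted over the list alone), with Aqp8 (3.34 ± 0.42) and Scnn1g, a sodium channel subunit (-2.72 ± 0.31). Aqp8 had 3 reads in all in BN with oil, and its BN read ratio was 20.7 with a counting interval from 6.82 to 102.6. In the steroid metabolism list 2 of 13 measured rose and 5 fell (2 and 6 adjusted over the list alone), with Akr1c14 (-0.97 ± 0.09) and Sts (-1.31 ± 0.17) falling. Among cytokines and chemokines 0 of 21 measured rose and 10 fell (0 and 10 adjusted over the list alone), with IL15 (-0.79 ± 0.12) and Tnfsf10 (-0.72 ± 0.12). With the gene length trend removed camera called this list below 0 (adjusted p = 0.0433, against 0.0835 without that step). For complement 3 of 20 measured rose and 4 fell (2 and 4 adjusted over the list alone), with C7 at 0.58 ± 0.12 and Serping1 at -0.76 ± 0.16.

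Camera called none of the cell type lists in the average over strains, where their medians ran from -0.46 for B and plasma cells to 0.54 for red blood cells. Of all tested genes 48.4% were called in that average. For uterine epithelium 4 of 19 measured rose and 5 fell (4 and 5 adjusted over the list alone), with Prom1 at 2.13 ± 0.12 and Foxa2, a gland transcription factor, at -1.18 ± 0.11. Among stromal fibroblast markers 2 of 16 measured rose and 2 fell (2 and 2 adjusted over the list alone), with Pdgfrb at -0.78 ± 0.12 and Vim at -0.47 ± 0.09. Among smooth muscle markers 1 of 16 measured rose and 1 fell (0 and 0 adjusted over the list alone), with Tpm2 at 0.33 ± 0.11 and Synm at -0.52 ± 0.20. For endothelium 1 of 16 measured rose and 6 fell (1 and 6 adjusted over the list alone), with Erg at -0.39 ± 0.08 and Emcn at 0.35 ± 0.08. For macrophages and dendritic cells 5 of 16 measured rose and 0 fell (1 and 0 adjusted over the list alone), with the scavenger receptor Cd163 at 0.96 ± 0.15 and Cd14 at 0.29 ± 0.09. Of T and NK cell markers 1 of 18 measured rose and 0 fell (1 and 0 adjusted over the list alone), Cd8a being the member that rose (1.20 ± 0.17). Of B and plasma cell markers 1 of 8 measured rose and 1 fell (1 and 1 adjusted over the list alone), namely Mzb1 (1.35 ± 0.25) and Cd22 (-1.02 ± 0.21). Among eosinophil, neutrophil and mast cell markers 1 of 12 measured rose and 2 fell (1 and 1 adjusted over the list alone), with Kit at -0.93 ± 0.10 and Tpsab1 at 1.36 ± 0.28. For red blood cells 1 of 7 measured rose and 0 fell (0 and 0 adjusted over the list alone), Hbb at 0.86 ± 0.29. For mesothelium 0 of 10 measured rose and 1 fell (0 and 0 adjusted over the list alone), Upk1b at -0.34 ± 0.12. Of squamous markers of cervix or vagina 0 of 6 measured rose and 2 fell (0 and 2 adjusted over the list alone), Col17a1 and Krt10 (-0.82 ± 0.20). Of oviduct and ciliated cell markers 2 of 7 measured rose and 3 fell (2 and 3 adjusted over the list alone), with Tubb4b at 1.22 ± 0.10 and Dnai1 at -1.85 ± 0.30. In the ovary list 0 of 8 measured rose and 1 fell (0 and 1 adjusted over the list alone), namely Fshr (-1.31 ± 0.34). In the nerve and Schwann cell list 1 of 11 measured rose and 4 fell (1 and 4 adjusted over the list alone), with Ngfr at 2.38 ± 0.27. Of skeletal muscle markers 3 of 11 measured rose and 3 fell (3 and 3 adjusted over the list alone), with Actn3 at -1.39 ± 0.14 and Tnnc2 at 1.20 ± 0.20. Of the ribosomal proteins 1 of 29 measured rose and 1 fell (1 and 0 adjusted over the list alone), with Rps14 at 0.49 ± 0.10 and Rpl3 at -0.28 ± 0.09.

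**Figure D4:**
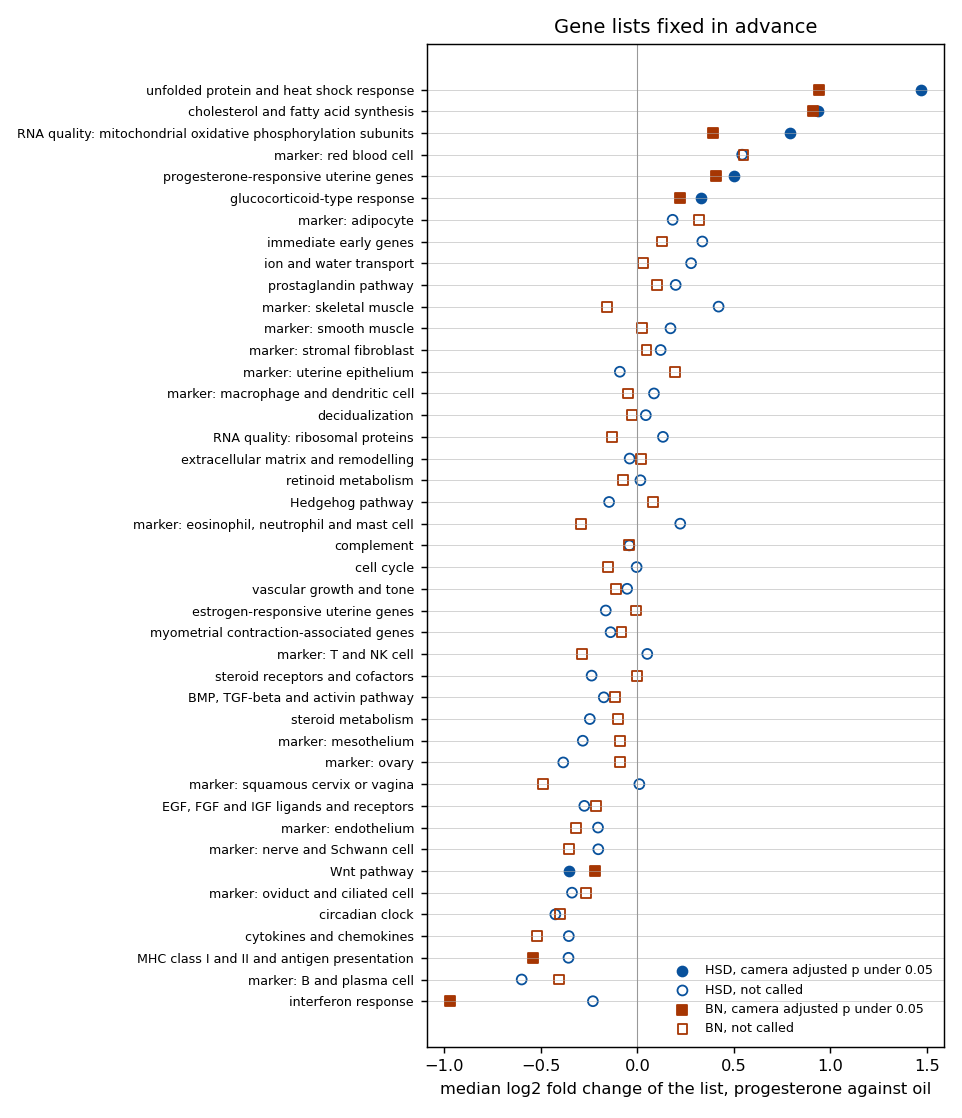
Median log2 fold change under progesterone of each of the 43 gene lists in HSD (circles) and BN (squares), filled where camera with the preset correlation gave an adjusted p under 0.05. The unfolded protein list has the highest median, 1.47 in HSD and 0.94 in BN, and the interferon list the lowest in BN, at -0.97. The cholesterol list stands at 0.91 in BN, and above the unfolded protein list there with exon reads (0.99 against 0.95).

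The strain difference of the progesterone change, BN minus HSD, asks whether the strains respond differently. Arnt2, a bHLH-PAS transcription factor (chromosome 1, 147327952 to 147484879), fell in both strains and less in BN, from 561 ± 58.1 to 82.3 ± 4.86 CPM in HSD and from 273 ± 18.1 to 122 ± 9.79 CPM in BN (n = 3). Il17re, a receptor subunit for interleukin 17C (chromosome 4, 208711257 to 208723904), rose in BN from 31.8 ± 3.58 to 75.4 ± 8.73 CPM. In HSD it stood at 34 ± 3.96 and 26.3 ± 0.634 CPM, a fall whose call was lost in 7 settings. Atp7b, a copper-transporting ATPase (chromosome 16, 74495179 to 74574801), rose more in HSD, from 1.54 ± 0.0790 to 26.1 ± 3.01 CPM, than in BN, from 1.97 ± 0.399 to 7.20 ± 1.71 CPM. RT1-A2, an MHC class I gene (chromosome 20, 7433433 to 7436985), rose in HSD from 136 ± 38.7 to 419.9 ± 99.1 CPM and fell in BN from 158 ± 35.9 to 97.7 ± 12.9 CPM. Class I genes differ in sequence and number between rat strains. The edgeR test called 8 genes, 4 in each direction, and 1133 had an unadjusted p under 0.05. The differences were 1.61 ± 0.15 for Arnt2 (edgeR adjusted p = 0.00198), 1.61 ± 0.17 for Il17re, 0.96 ± 0.13 for Emid1 (82.6% of reads in introns), and 1.22 ± 0.19 for Clu. They were -1.71 ± 0.26 for Csrp2, -1.73 ± 0.26 for the mitochondrial ornithine transporter Slc25a15 (chromosome 16, 74169024 to 74189301), -2.22 ± 0.30 for Atp7b and -2.32 ± 0.32 for RT1-A2. Next in each direction were Cox10 (0.93 ± 0.15, edgeR adjusted p = 0.0527) and Igsf11 (-1.66 ± 0.27, edgeR adjusted p = 0.0621), which did not pass. Of the genes called in opposite directions, Myo19 (0.68 ± 0.15), Sftpd (-1.77 ± 0.41) and Slc28a3 (1.0 ± 0.21) did not pass this test. Myo19 and Slc28a3 changed direction in HSD when exon reads were counted, and Slc28a3 was then called as rising there (edgeR adjusted p = 0.000497). Of the 8 calls, those of Arnt2 and Il17re held in every alternative and with each library left out. DESeq2 called 119 genes, limma voom with quality weights 26 and a fit with 1 surrogate variable 44. Upper-quartile scaling gave 5 higher and 3 lower. The count was 17 without HSD oil replicate 2, 16 without HSD progesterone replicate 2, and 13 without HSD progesterone replicate 3. It was 5 without HSD progesterone replicate 1 or BN oil replicate 1, 4 without BN oil replicate 3 or BN progesterone replicate 1, and 2 without HSD oil replicate 3, BN oil replicate 2 or BN progesterone replicate 3.

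Camera placed 10 lists apart in the strain difference. None held with an estimated correlation, where adjusted p ranged from 0.584 to 0.765, and fry called none. Interferon response genes had a median difference of -0.74 (camera adjusted p = 3.78e-13, adjusted p = 0.745 with an estimated correlation), with Mx2 at -0.98 ± 0.27 and Isg15 at -1.26 ± 0.38. Adjusted over the list alone 9 of its members passed, over all genes none. Unfolded protein genes had a median of -0.37 (camera adjusted p = 1.46e-08, adjusted p = 0.584 with an estimated correlation), with Hsp90b1 at -0.76 ± 0.19 and Pdia4 at -0.60 ± 0.16. Of its members 8 passed over the list alone. The remaining lists called below 0 were oxidative phosphorylation subunits (median -0.40), ribosomal proteins (-0.28), MHC and antigen presentation (-0.22), macrophage and dendritic cell markers (-0.28) and the glucocorticoid-type response (-0.12). The Wnt (0.14), Hedgehog (0.18) and BMP, TGF-beta and activin (0.24) lists lay above 0. Across genes the strain difference rose with exon length (Spearman's rho = 0.234). With that trend removed the medians were -0.28 for oxidative phosphorylation subunits, -0.16 for ribosomal proteins and 0.10 for Hedgehog. Scaled by library size alone the glucocorticoid-type median was -0.04, that of MHC -0.14 and that of Wnt 0.22. With exon reads the last pair stood at -0.38 and 0.09. Without HSD progesterone replicate 3 the camera adjusted p was 0.358 for Hedgehog, 0.340 for Wnt, 0.382 for BMP, TGF-beta and activin, and 0.0735 for the glucocorticoid-type response. Without HSD progesterone replicate 2 it was 0.182 for macrophages and dendritic cells. Without BN oil replicate 2 it was 0.0619 for Hedgehog, 0.0624 for Wnt, 0.0989 for BMP, TGF-beta and activin, and 0.0781 for macrophages and dendritic cells. Without HSD oil replicate 3 it was 0.0533 for Hedgehog and for the glucocorticoid-type response, and the latter was 0.108 without BN oil replicate 1 and 0.0971 without BN progesterone replicate 1. The BMP, TGF-beta and activin list stood at 0.0581 without HSD oil replicate 1 and 0.0623 without BN progesterone replicate 3, and macrophages and dendritic cells at 0.0581 without BN progesterone replicate 2.

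BN against HSD under oil asks which genes differ between the strains before treatment. Hbb-b1, a beta globin (chromosome 1, 175104276 to 175111736), stood at 27.4 ± 5.65 CPM in HSD and 1.63 ± 0.504 CPM in BN (n = 3), with 75.2% of its reads placed uniquely. Rbm46, an RNA-binding protein (chromosome 2, 201245864 to 201288843), stood at 4.15 ± 0.219 and 25.4 ± 3.13 CPM, and Hfm1, a meiotic helicase (chromosome 14, 3879476 to 3958032), at 2.70 ± 0.778 and 24 ± 4.52 CPM. The carbonic anhydrase Car4 (chromosome 10, 72179405 to 72188138) stood at 7.70 ± 3.44 and 0.181 ± 0.176 CPM. The edgeR test called 893 genes, 368 higher and 525 lower in BN. Higher in BN, in log2, were also Agbl4_2 (5.78 ± 0.48), the secretory granule protein Scg3 (3.67 ± 0.48) and Vom2r37 (3.16 ± 0.24, with 99.5% of reads in introns). So were Aoc1, diamine oxidase (2.95 ± 0.73), Emr4 (2.92 ± 0.30, with 99.5% of reads in introns) and Glt1d1 (2.57 ± 0.46). Lower were Fam111a (-6.85 ± 1.47), Rps10l1 (-3.67 ± 0.21) and Rpl6_1 (-3.28 ± 0.11), with 36.2 and 46.7% of reads of the last pair placed uniquely and so uncertain levels. Also lower were Ly6g6e (-3.38 ± 0.45), the mitochondrial creatine kinase Ckmt1b (-3.02 ± 0.45) and Sez6l (-2.79 ± 0.39). In the HSD oil libraries Fam111a stood at 45.9, 135 and 1.73 CPM. Its call was lost in 7 settings, voom and each of the BN oil libraries left out among them. That of Aoc1 was lost in 10, each of the oil libraries left out among them, and that of Scg3 with exon reads. The count was 588 without HSD oil replicate 1, 535 without HSD oil replicate 3, and 516, 450 and 436 without BN oil replicates 1, 2 and 3. It was 1964 with voom, 1803 with 1 surrogate variable, 538 with exon reads and 504 on log2 RPKM.

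Red blood cell markers were the list farthest from 0 under oil, where 0 of 7 measured were higher and 4 lower (0 and 5 adjusted over the list alone) in BN (camera adjusted p = 4.65e-09, and adjusted p = 0.292 with an estimated correlation). Among them were Hba2 (-2.62 ± 0.42) and Hba1 (-2.34 ± 0.41). Of the uterine epithelium markers 0 of 19 measured were higher and 5 lower (0 and 9 adjusted over the list alone; camera adjusted p = 1.14e-05, and adjusted p = 0.831 with an estimated correlation). Among them were Krt7 (-0.86 ± 0.17) and Krt18 (-0.62 ± 0.13). Among eosinophil, neutrophil and mast cell markers 3 of 12 measured were higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.00404, and adjusted p = 0.664 with an estimated correlation). These are the mast cell genes Ms4a2 (1.81 ± 0.26), Mcpt2 (3.49 ± 0.60) and Cpa3 (1.13 ± 0.22). Camera also placed above 0 the nerve and Schwann cell (adjusted p = 0.00955), interferon response (0.0114), stromal fibroblast (0.0147), vascular growth and tone (0.0147) and smooth muscle lists (0.0221). With an estimated correlation the adjusted p of each lay between 0.845 and 0.886. Their called members were Uchl1 (2.25 ± 0.20) and Cdh19 for nerve, Cxcl10, Irf1 and Gbp2 for interferon, Mgp for stroma, and Casq2 and Myocd for smooth muscle. No vascular gene passed in edgeR, where 2812 of all genes had an unadjusted p under 0.05. The interferon call ended without HSD oil replicate 3 (camera adjusted p = 0.164) or BN oil replicate 2 (0.428). The smooth muscle call ended without HSD oil replicate 2 (0.303) or BN oil replicate 1 (0.171). The nerve call ended without HSD oil replicate 3 (0.0974), the vascular call without HSD oil replicate 2 (0.0954) and the stromal call without BN oil replicate 1 (0.0546).

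BN against HSD under progesterone asks the same between treated animals. Hbb-b1 was again lower in BN, at 39.5 ± 7.58 CPM in HSD and 2.07 ± 0.929 CPM in BN (n = 3). The MHC class I gene RT1-A2 stood at 419.9 ± 99.1 and 97.7 ± 12.9 CPM and RT1-CE5 at a log2 difference of -2.68 ± 0.20. Rbm46 stood at 4.72 ± 1.02 and 28.8 ± 2.57 CPM, and Car4 at 8.52 ± 4.95 and 0.0982 ± 0.0372 CPM. Agbl4_2 had 2 reads in all in HSD with progesterone and 261 in BN, a ratio of 118.3 after depth with a counting interval from 32.4 to 982. The edgeR test called 900 genes, 381 higher and 519 lower in BN. Scaling by library size alone gave 586 higher and 376 lower. Called in the same direction under both treatments were 189 higher and 202 lower genes, where independent lists would share 8.93 and 17.4. These comparisons share no libraries. Igsf23, Arnt2 and Csrp2 were called in opposite directions under oil and progesterone, at -0.48, -1.04 and 0.92 against 0.57, 0.57 and -0.79. The call of Igsf23 was lost in 16 settings under oil and in 18 under progesterone, there without each of the 12 libraries. Under progesterone those of Arnt2 and Csrp2 were lost without BN progesterone replicate 1 or 3. That of Csrp2 was also lost without HSD progesterone replicate 3, with exon reads and on log2 RPKM, and under oil without HSD oil replicate 3. Other genes kept the direction they had under oil: Scg3 (2.5 ± 0.43), Vom2r37 (2.42 ± 0.23), Hfm1 (2.83 ± 0.24), Aoc1 (2.94 ± 0.71), Emr4 (1.06 ± 0.27) and Glt1d1 (2.24 ± 0.49) were higher. Fam111a (-8.61 ± 1.42), Rps10l1 (-3.92 ± 0.21), Ly6g6e (-3.38 ± 0.44), Rpl6_1 (-3.31 ± 0.11), Ckmt1b (-2.65 ± 0.43) and Sez6l (-1.86 ± 0.39) were lower. Under progesterone the call of Emr4 was lost in 11 settings, unique reads among them, that of Aoc1 in 6, Sez6l in 4 and Glt1d1 in 3. That of Scg3 was lost with exon reads and that of Fam111a with voom. The count was 341 without BN progesterone replicate 1, 406 without BN progesterone replicate 3 and 1515 without HSD progesterone replicate 2. It was 1519 with DESeq2, 1688 with voom, 1849 with 1 surrogate variable, 566 with exon reads, 481 on log2 RPKM and 409 in a fit to these groups alone.

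Under progesterone camera placed 14 lists apart between the strains, and adjusted p with an estimated correlation ranged from 0.110 to 0.711 over them. Of red blood cell markers 0 of 7 measured were higher and 4 lower (0 and 5 adjusted over the list alone; camera adjusted p = 3.77e-10). Of MHC and antigen presentation genes 1 of 22 measured were higher and 5 lower (1 and 6 adjusted over the list alone; camera adjusted p = 1.07e-07). Of oxidative phosphorylation subunits 0 of 23 measured were higher and 5 lower (0 and 17 adjusted over the list alone; camera adjusted p = 1.42e-07), with Cox6a1 at -0.44 ± 0.10. Of ribosomal proteins 0 of 29 measured were higher and 1 lower (0 and 2 adjusted over the list alone; camera adjusted p = 3.86e-07). Both lists stood highest in HSD progesterone replicate 3, the library apart on component 3. This strain difference also rose with exon length (Spearman's rho = 0.253). Of unfolded protein genes 0 of 24 measured were higher and 3 lower (0 and 5 adjusted over the list alone; camera adjusted p = 0.000550), namely Creld2 (-1.15 ± 0.14), MANF (-0.70 ± 0.14) and Sdf2l1 (-1.06 ± 0.23). Of T and NK cell markers 0 of 18 measured were higher and 2 lower (0 and 6 adjusted over the list alone; camera adjusted p = 0.000814), Cd8a (-2.31 ± 0.23) and Lck (-0.68 ± 0.17). Of interferon genes 1 of 23 measured were higher and 3 lower (1 and 11 adjusted over the list alone; camera adjusted p = 0.00509), with Psmb8 at -0.91 ± 0.21 and Rsad2 at 0.91 ± 0.22. Of cholesterol synthesis genes 0 of 26 measured were higher and 3 lower (0 and 4 adjusted over the list alone; camera adjusted p = 0.00811). Of epithelial markers 0 of 19 measured were higher and 3 lower (0 and 5 adjusted over the list alone; camera adjusted p = 0.00811), and of granulocyte and mast cell markers 4 of 12 measured were higher and 0 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.0161). The extracellular matrix (camera adjusted p = 0.00811), stromal fibroblast (0.0249), vascular (0.0366) and myometrial (0.0400) lists lay above 0. Without HSD progesterone replicate 3 these values were 0.453, 0.346, 0.440 and 0.346, and 0.115 for granulocytes and mast cells. With the gene length trend removed the vascular and myometrial calls ended (camera adjusted p = 0.0740 and 0.116). The interferon call ended without HSD progesterone replicate 2 (camera adjusted p = 0.112) and the cholesterol call without HSD progesterone replicate 1 (0.179). Without BN progesterone replicate 3 the values were 0.123 for extracellular matrix, 0.133 for stroma and 0.123 for vessels, and without BN progesterone replicate 1 they were 0.107 for vessels and 0.0553 for myometrium.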

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

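Chosen only after the result was seen were the tests of the smaller change in BN, of the genes called between the strains and of the library that stood apart, exon reads, scaling by library size alone and removal of a gene length trend among them, while the fits that leave out a library, the unique reads and the splits of the libraries were fixed before.

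Progesterone changes were smaller in BN than in HSD, with a median BN to HSD ratio of 0.775 over the 7595 genes called across strains, 73.1% of them smaller in BN. For the strain difference of these genes signed by their direction, the rotation test fry gave p = 0.0196, and p = 0.0615 on simulated equal responses, while the permutation test of strain within treatment, not exact for a difference in response, gave p = 0.07, with 14 of 200 labellings as large. The fry value ranged from 0.0042 to 0.0649 with 1 library left out, the highest without BN oil replicate 2, and was 0.0507 with exon reads. A scaling difference between the strains would move rising and falling genes the same way, whereas the median strain difference was -0.14 for genes that rose and 0.132 for genes that fell. Without HSD progesterone replicate 3 the ratio was 0.805 and with the gene length trend removed 0.779, so neither accounts for it alone. A smaller response in BN, the larger spread in HSD, tissue composition and a batch that follows strain may each remain. The fry and permutation tests do not exclude chance either.

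Genes called between the strains could reflect HSD reads lost against a reference made from BN, yet 41.2% of the genes called under oil were higher in BN (95% interval 38.0 to 44.5, genes taken as independent), where lost reads would put most of them higher. Without BN oil replicate 1 the share was 49.2% (44.8 to 53.6), and under progesterone it was 42.3%, or 60.9% when scaled by library size alone, so lost reads are not excluded. The median ratio of exon to gene log2 change was 0.998, and of 793 called genes testable with exon reads 781 kept their direction and 485 were called. With uniquely placed reads 95.9% were called, and more than 50% of reads lay in introns for 32.6% of called and 21.8% of other genes. Sequence differences at single genes remain open too, because no genome sequence was used.

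HSD progesterone replicate 3 stood apart on component 3, and the biological coefficient of variation of its group was 0.222, against 0.159 in HSD with oil and 0.112 in each BN group, and 0.156 without it. With the gene length trend removed the group's value was 0.217, so a length trend does not account for it. A smaller share of smooth muscle alone was taken to leave stromal markers in place, whereas they lay at the 0.11 percentile of matched lists beside smooth muscle at the 0 percentile. Mesothelium lay at the 0.49, nerve at the 0.78 and skeletal muscle at the 0.11 percentile. Uterine epithelium lay at the 49.3 and oviduct and ciliated cell markers at the 87.1 percentile. These values cannot exclude a piece with less of a layer that holds several of the low cell types. A swapped label is not favoured, since its distance to its own group on components 1 and 2 was 15.9, against 97.4 and 111 to the oil groups of HSD and BN and 68.8 to BN with progesterone. A mixed difference of tissue piece and RNA may remain, with oxidative phosphorylation subunits at the 100 percentile of matched lists and endothelium at the 0.08 percentile. Introns held 22.95% of the reads of replicate 3, against 21.09 and 19.96% in replicates 1 and 2. Replicates 2 and 3 carry the same barcode, so they cannot have been sequenced in the same pool. A difference of sequencing run or pool therefore remains too. Without replicate 3, 13 genes were called for the strain difference against 8 with it.

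Of 10 splits of the 6 libraries, the real grouping gave the most calls in HSD (6133 against 2 in the highest other), BN (4045 against 0), the strains under oil (893 against 0) and the strains under progesterone (900 against 0), so that 1 split reached the real count in each, too few splits for a share under 0.05. Over both strains 1 of 100 relabellings, the real grouping included, reached 7595 calls, the highest other giving 2619. For the strain difference 2 of 100 reached 8 calls, the real grouping included, and the highest other gave 16. Other groupings mix libraries of both treatments or both strains within groups, which can raise the spread and lower the calls. They therefore do not show how many of the calls arose by chance.

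The strain difference of the progesterone change was 1.61 for Arnt2 and 1.61 for Il17re, both held with every library left out. It was 0.96 for Emid1, lost in 10 settings, 1.22 for Clu, lost in 9, -2.22 for Atp7b, lost in 6, -2.32 for RT1-A2, lost in 5, -1.73 for Slc25a15, lost in 9, and -1.71 for Csrp2, lost in 12.

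For the lists, camera adjusted p of the strain difference was 3.78e-13 for interferon response, 1.46e-08 for unfolded protein and heat shock, 5.3e-08 for oxidative phosphorylation subunits, 8.94e-06 for ribosomal proteins and 8.13e-05 for MHC and antigen presentation. It was 0.00999 for macrophages and dendritic cells, 0.013 for the glucocorticoid-type response, 0.013 for Wnt, 0.0134 for Hedgehog and 0.0247 for BMP, TGF-beta and activin. None of the 10 held with an estimated correlation, where adjusted p lay between 0.584 and 0.765, and fry called none (adjusted p 0.261 to 0.596).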

How the results depend on the processing

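Exon reads, scaling by library size alone and removal of the gene length trend are tests chosen only after the result was seen; the other settings were fixed before the data were examined. No paired analysis was possible because no animal or replicate number joins libraries across groups, and groups of 3 were not tested for single far samples.

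In BN 4045 genes were called, against 6739 with limma voom and quality weights and 6186 with 1 surrogate variable. Leaving out libraries gave 2606 (BN oil replicate 3) to 5055 (HSD progesterone replicate 3). The 8 calls of the strain difference became 119 with DESeq2, 26 with voom and 44 with a surrogate variable. They ran from 2 without HSD oil replicate 3 to 17 without HSD oil replicate 2.

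Between the strains under oil 893 calls became 1964 with voom, 1803 with a surrogate variable, 538 with exon reads and 504 on log2 RPKM. Leaving out libraries they ran from 436 without BN oil replicate 3 to 1327 without HSD progesterone replicate 3. Under progesterone 900 became 1519 with DESeq2, 409 with these groups alone, 1688 with voom, 1849 with a surrogate variable, 566 with exon reads and 481 on log2 RPKM. Leaving out libraries they ran from 341 without BN progesterone replicate 1 to 1515 without HSD progesterone replicate 2.

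The correlation between strains, 0.814, was 0.413 with no filter, 0.836 with the CPM filter, 0.790 with voom and 0.858 on log2 RPKM. It was 0.741 (without BN oil replicate 1) to 0.787 (without BN oil replicate 2) with a library left out. Calls in HSD stayed between 4774 and 6583 and averaged calls between 6821 and 8071 with a library left out, and genes called in both strains between 2324 and 3874.

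With exon reads and on log2 RPKM, Myo19 in HSD turned to 0.38 (edgeR adjusted p = 0.0763) and 0.24 (limma adjusted p = 0.242). Averaged over strains it turned to 0.55 (edgeR adjusted p = 0.00154) and 0.42 (limma adjusted p = 0.00848). Slc28a3 in HSD turned to 1.89 (edgeR adjusted p = 0.000497) and 1.25 (limma adjusted p = 0.00179). Most reads of both genes lie in introns, which exon counting leaves out.

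Of the named calls, 41 of 51 in HSD, 32 of 46 in BN, 45 of 52 averaged, 2 of 8 for the strain difference, 14 of 19 under oil and 10 of 19 under progesterone held in every setting and with each library left out. Of 258 list results 51 weakened with an estimated correlation, and with fry 26 weakened and 17 strengthened. Only results called by camera could weaken. Those were 6 in HSD, 8 in BN, 7 averaged, 10 for the strain difference, 8 under oil and 14 under progesterone. With an estimated correlation 1, 0, 1, 0, 0 and 0 lists were called in the same order, so nearly all camera calls were lost.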

Other observations

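Which genes to set beside each other below, and the tests of Fam111a, Slc25a15 and Atp7b, were chosen only after the result was seen, while the list tests were fixed before.

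Clock genes changed in both directions in the uterus of both strains. In the circadian clock list, averaged over strains, 5 of 18 measured rose and 9 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.358). Dbp, a clock output transcription factor, fell from 335 ± 60.0 to 64.5 ± 10.8 CPM in HSD and from 251 ± 34.1 to 61.2 ± 16.1 CPM in BN (n = 3). Nr1d1, the repressor of ARNTL, fell from 183 ± 65.6 to 27.1 ± 7.90 and from 147 ± 24.8 to 28.9 ± 11.5 CPM. Per3 fell as well (-0.94 ± 0.07), and ARNTL (1.34 ± 0.14), Nfil3 (2.13 ± 0.18) and Cry1 (1.07 ± 0.11) rose. The hour of the day at which oil and progesterone animals were killed is not given in the sources used here.

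Each gene named in this paragraph was called in the same direction in both strains. Averaged over strains, 3868 of all 15697 tested genes rose and 3727 fell. Among prostaglandin pathway genes 5 of 20 measured rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.121). The share of this list that rose was thus near that of all genes. Ptgs1, cyclooxygenase 1, rose from 92.5 ± 10.7 to 239.9 ± 11.1 CPM in HSD and from 76.9 ± 4.21 to 238 ± 31.8 CPM in BN. The same list held Ptges2 at 0.77 ± 0.09 and Cbr1 at 0.88 ± 0.11. In the retinoid metabolism list 6 of 19 measured rose and 7 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.928). The retinol transporter Stra6 (0.96 ± 0.14) and the hydroxylase Cyp26a1 (2.49 ± 0.42) rose. The retinal-forming Dhrs9 (-2.73 ± 0.44) and the retinoic acid-forming Aldh1a3 (-1.36 ± 0.23) fell. For extracellular matrix and remodelling 8 of 37 measured rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.928). The protease Mmp7 rose from 1.25 ± 1.29 to 41.9 ± 16.7 CPM in HSD and from 2.71 ± 2.41 to 53.6 ± 13.3 CPM in BN. Col12a1 stood at 1.40 ± 0.15 and Mmp11 at -1.22 ± 0.12. Of the adipocyte markers 3 of 10 measured rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.591). Adipoq, adiponectin (1.88 ± 0.12), and Lpl (0.46 ± 0.06) rose and Lipe (-0.55 ± 0.11) fell.

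Slc25a15 and Atp7b lie on the same chromosome (chromosome 16, 74169024 to 74189301; chromosome 16, 74495179 to 74574801), and both rose less in BN than in HSD, with strain differences of -1.73 ± 0.26 and -2.22 ± 0.30. Sequence variants near them were not analysed here.

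Fam111a differed among the outbred HSD animals as well as between strains. Its levels were 45.9, 135 and 1.73 CPM in HSD with oil and 202, 119 and 459.6 CPM in HSD with progesterone, while no BN library exceeded 0.722 CPM.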
